A study of Arabidopsis thaliana with 14 samples.

How the data were processed

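Leaves of 4-week-old Arabidopsis plants of accession Ws-4 were syringe-infiltrated with Xcc147 or left uninoculated, and biotinylated cRNA made from total RNA was hybridised to Affymetrix ATH1 arrays, per the labels' protocols. The authors deposited 1 linear signal intensity per probe set and array, computed with MAS5 per the submitters' processing notes which name no version, and no detection calls came with it. The deposited intensity values have the same trimmed mean on each array (100), and no further normalization was applied. Per the labels, material was pooled before extraction where needed. The 14 arrays fell into 8 groups of 1 or 2 by line and harvest, and 4 experiment numbers. Wild-type samples at 90-105 min were not analysed here. The number of arrays limits the precision, since 6 groups have 2 arrays and 2 have 1.

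Of 22810 probe sets, the 64 Affymetrix controls were left out of tests, and a probe set was tested if its signal lay above the 40th percentile of the array (16.6 to 19.9) on at least 2 arrays, which left 15615. Values were taken as log2(signal + 16), and fold changes on this scale understate the changes of genes with low signal. For named genes at or below that percentile on all arrays of the lower group, the percentile took the place of the signal, and the change is given as at least the smallest of this, its ratio of mean signals and the fitted value, a form chosen after the results were seen. Genes were named from the platform's table, through gene identifiers, with symbols of RefSeq (TAIR10.1). The table paired 13513 probe sets with 1 gene, 503 with several and did not list 8730; 13436 of those with 1 gene were found in RefSeq. Of the tested probe sets 8552 (54.8%) had 1 gene and 6748 were not listed, and these are not given by identifier in the text. Where a gene had several probe sets, the one with the highest mean signal stood for it.

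Comparisons were tested in R 4.3.3 with limma 3.58.1: 1 mean per group over all 14 arrays (residual degrees of freedom 6, prior degrees of freedom 3.59), moderated with a trend, and adjusted by Benjamini and Hochberg at 0.05. Every adjusted p of a probe set is limma's two-sided test. Groups of 1 array were assumed to vary like the others. The averaged difference of overexpressor and wild type used 10 arrays with harvest and line as terms. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists with at least 3 tested members and all comparisons, and again with an estimated correlation. Tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined; the 20 gene families, the comparisons between later harvests and the comparison of experiments were added afterwards. The rule named, among probe sets with 1 gene past the threshold and of the same sign in each same-experiment pair, the 10 largest rises and 10 largest falls (5 and 5 at 6 h), up to 4 called members of each list and, where none was called, up to 2 members with the highest signal.

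The labels' experiment numbers pair wild-type and overexpressor samples, because each number marks a shared experiment. Deviations from the group means of same-numbered arrays correlated at r = -0.0121 to 0.744 over 10 pairs of groups, 6 of them over 0.1. The fit without the block was kept as written and the fit with it given where it changed a call. Alternatives were pseudocounts of 1 and 64, no filter or one at the 60th percentile, median centring, quantile normalization, no trend, a 2-fold minimum, experiment as a fixed or random block, the arrays of the compared groups alone and each array left out in turn.

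The test was checked on simulated data drawn around the overall mean of each real probe set with its fitted spread, with 200 of 15615 probe sets changed in each of 5 draws. Each array was drawn independently, here and in the draws below, so they hold no deviation shared by the arrays of an experiment. Of 2-fold and 4-fold changes it found 19.8% and 85.6% for the wild type at 2-4 h against T0 (7.05% of calls false), 4.4% and 70.2% for the wild type at 6 h against T0 (4.36% false), 20% and 86.8% between the lines at 2-4 h (3.09% false), 1.4% and 38.4% at 6 h (6.57% false) and 80.6% and 97.8% for the average over harvests (6.01% false). Overlaps of comparisons that share T0 arrays were set against 50 simulated draws of unchanged groups. That of the screen was set against as many draws around the mean of both lines at T0, 2-4 h and 6 h and of antisense line and overexpressor at 90-105 min, which keep the response and hold no difference between lines. For both, lists of the observed sizes were also taken from the top of each draw. These steps were chosen after the results were seen, apart from the draws of unchanged groups. The 3' to 5' signal ratios of the control genes ranged over the arrays from 0.818 to 1.07 for GAPDH, 1.26 to 1.75 for actin and 1.20 to 1.66 for ubiquitin, whose ratio was higher on each T0 array than on each array at 2-4 h or 6 h.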

Results

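Affymetrix ATH1 arrays measured transcript signal in leaves of 4-week-old Arabidopsis plants of accession Ws-4. The 14 arrays analysed here came from the wild type (5 arrays), a line that overexpresses AtMYB30, a MYB transcription factor (7 arrays), and an AtMYB30 antisense line (2 arrays). Leaves were taken before inoculation (T0) or 90-105 min, 2-4 h or 6 h after syringe infiltration with the Xanthomonas strain Xcc147. The overexpressor T0 samples are called not inoculated in their titles and sources, while their inoculation entry names Xcc147, and they were taken as not inoculated. Each of wild-type T0, wild-type 2-4 h, overexpressor T0, overexpressor 90-105 min, overexpressor 2-4 h and antisense 90-105 min had 2 arrays, and each line had 1 array at 6 h apart from the antisense line, which had none there. Replicates 1 and 2 of the wild type and the overexpressor are experiments 1 and 2 of the labels, which name experiment 2 as a biological replicate, and the antisense arrays are experiments 3 and 4. The median signal was 31.6 to 36.1 per array, and log2 values of replicate arrays correlated across probe sets at r = 0.898 to 0.968. The number of arrays limits the precision, and no array came from mock-infiltrated leaves, so a change from T0 holds the response to infiltration and to the hours that passed as well as to the bacterium.

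The first question was whether the lines carried the AtMYB30 level their labels state. No probe set in the gene table was paired with AtMYB30, and the table left 8730 probe sets unlisted. The AtMYB30 transcript could thus not be identified on the arrays, and the labels could not be checked by it. A single probe set without a gene name was singled out after its values were seen because its signal followed the lines. It was 29.4 to 76.1 on the 5 wild-type arrays, 1709 to 2868 on the 7 overexpressor arrays and 13.2 and 59.7 on the 2 antisense arrays. Which transcript it detects is not stated in the gene table, and it is called the unnamed probe set here. In the plot of the lines its overexpressor arrays lay above every other array.

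**Figure D1:**
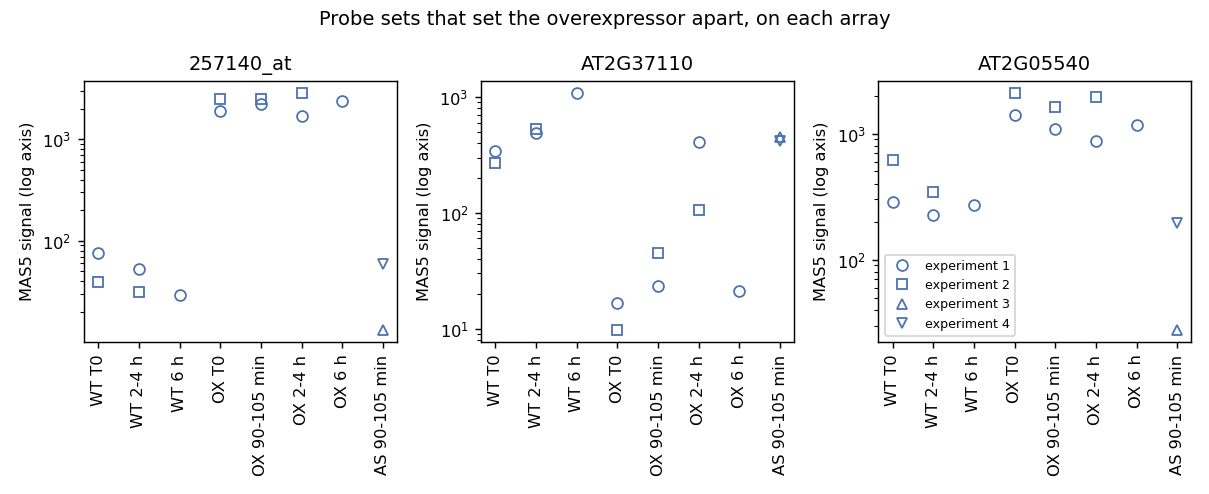
MAS5 signal (log axis) of the unnamed probe set, AT2G37110 and AT2G05540 on each of the 14 arrays, grouped by line and harvest; each point is 1 array. The 7 overexpressor arrays of the unnamed probe set sit between 1709 and 2868 and the other arrays at 76.1 or less.

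Wild-type leaves were compared between 2-4 h and T0 to find the genes that respond to Xcc147. The signal of AT2G43620, a chitinase-family gene, went from 49.8 ± 32.03 to 3400.3 ± 22.1 (mean ± SD, n = 2 each), a log2 change of 5.79 ± 0.33 (SE). AT2G38870, a protease inhibitor gene, went from 85.9 ± 42.99 to 2894 ± 44.7 (4.90 ± 0.33), and the peroxidase gene AT5G64120 from 81.8 ± 37.5 to 2699.6 ± 528 (4.84 ± 0.32). AT5G48570, which encodes an FKBP-type peptidyl-prolyl isomerase, rose by 4.74 and AT4G22470 by 4.40. Other genes had T0 signals at or below the 40th percentile of the array (16.6 to 19.9), which cannot be told from background, so where this holds for both T0 arrays only a lower bound of the measured mean change, without its error, is given, here and below. Where it holds for 1 of 2 the change is given as fitted and so marked, and is no bound. The small heat shock protein gene AT2G29500 rose by at least 5.10, the wall-remodelling gene XTH18 by at least 4.64, AT1G57630, a TIR-domain gene, by at least 4.63, AT1G49000 by at least 4.47 and AT2G17740 by 4.49 as fitted (1 of 2). AT1G19960 fell from 533 ± 62.01 to 47 ± 31.1 (-3.21 ± 0.56), AT4G18570 and AT4G02630 fell with log2 changes of -1.72 and -1.70, and AT5G59670, at or below that percentile on both 2-4 h arrays, with -1.84 or lower. All 7 measured genes of the early immune list rose, among them ZAT10 (3.61), a zinc finger regulator, the U-box ubiquitin ligase genes PUB22 (at least 3.42) and PUB23 (3.31 as fitted, 1 of 2), and the receptor-like cytoplasmic kinase gene BIK1 (2.32); adjusted over the list alone the count was also 7. As a set they stood above the other genes (camera adjusted p = 3.03e-11; adjusted p = 0.0401 with an estimated correlation). The 3' to 5' signal ratio of the ubiquitin control moved with inoculation as well: it was 1.48 to 1.66 on the 4 T0 arrays of both lines and 1.22 to 1.44 on the 6 arrays at 2-4 h and 6 h. Those of GAPDH (0.860 to 0.924 and 0.818 to 0.992) and actin (1.49 to 1.62 and 1.32 to 1.72) overlapped. WRKY53, a transcription factor gene of the salicylic acid list, rose by 3.62, and CCR2, which encodes a cinnamoyl-CoA reductase of lignin synthesis, by at least 2.49.

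In limma 781 probe sets rose and 279 fell between T0 and 2-4 h in the wild type (1060 of 15615 tested), and each changed the same way in both experiments. The experiments are the replicates of the test, so a call nearly requires this and it is no separate replication. The adjusted p of the rises named was 6.83e-05 (AT2G43620) to 0.00637 (AT5G48570), and that of AT1G19960 was 0.00934. The count was 499 without wild-type T0 replicate 1, 599 without T0 replicate 2, 519 without 2-4 h replicate 1 and 367 without 2-4 h replicate 2, when a lone array is assumed to vary like the other groups. Among the 10 largest fitted rises with a name the call of AT5G48570 alone ended in this way (4.18 without wild-type 2-4 h replicate 2); of the 10 largest fitted falls 7 ended, that of AT1G19960 with log2 changes of -3.10 without wild-type T0 replicate 2 and -2.69 without wild-type 2-4 h replicate 1.

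At 6 h the wild type, with 1 array, was compared with T0 for the later response. UGT76B1, a glycosyltransferase gene of defence signalling, had a signal of 1714 at 6 h and lay below the 40th percentile on both T0 arrays, a log2 rise of at least 6.53. AT1G57630, AT2G32190 and AT2G29500, also below it there, rose by at least 6.21, 6.14 and 5.99, and AT1G56060 (1 of 2) by 5.91 as fitted. AT5G35970 fell from 1521 ± 527 to 126 (-3.39 ± 0.51), the manganese transporter gene MTP11 from 274 ± 12.5 to 30 (-2.66 ± 0.21) and AT1G15260 with a log2 change of -2.63. Of the early immune list 6 of 7 rose, with ZAT10 at 3.43, PUB23 at 2.80 as fitted (1 of 2), BIK1 at 2.07 and PUB24 at 1.87; 6 passed adjusted over the list alone (camera adjusted p = 3.35e-06; adjusted p = 0.133 with an estimated correlation). AT2G04400, the gene of indole-3-glycerol phosphate synthase on the path to tryptophan, rose by 2.95. The ubiquitin 3' to 5' ratio was 1.22 on the 6 h array and 1.57 on average at T0.

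In limma 1261 probe sets rose and 1069 fell at 6 h in the wild type, a share of rises of 54.1% that became 64.2% (1417 and 790) with each array centred on its median. The adjusted p was 1.86e-04 for UGT76B1 and 0.00285 for AT5G35970. Of the probe sets that rose, 642 had also risen at 2-4 h, where independent lists give 63.1. Unchanged simulated groups against the same T0 arrays had a mean of 0 calls in both, and lists of the observed sizes taken from the top of them shared 244 on average and at most 273. A further 221 fell at both (19.1 from independent lists, 104 on average and at most 121 from simulated lists of the same sizes). Part of the excess over independent lists may thus come from the shared T0 arrays. The 6 h array has no replicate and is assumed to vary like the other groups, and without wild-type T0 replicate 2 the count was 1342; of the 5 largest fitted falls 2 ended without 1 array or another.

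**Figure D2:**
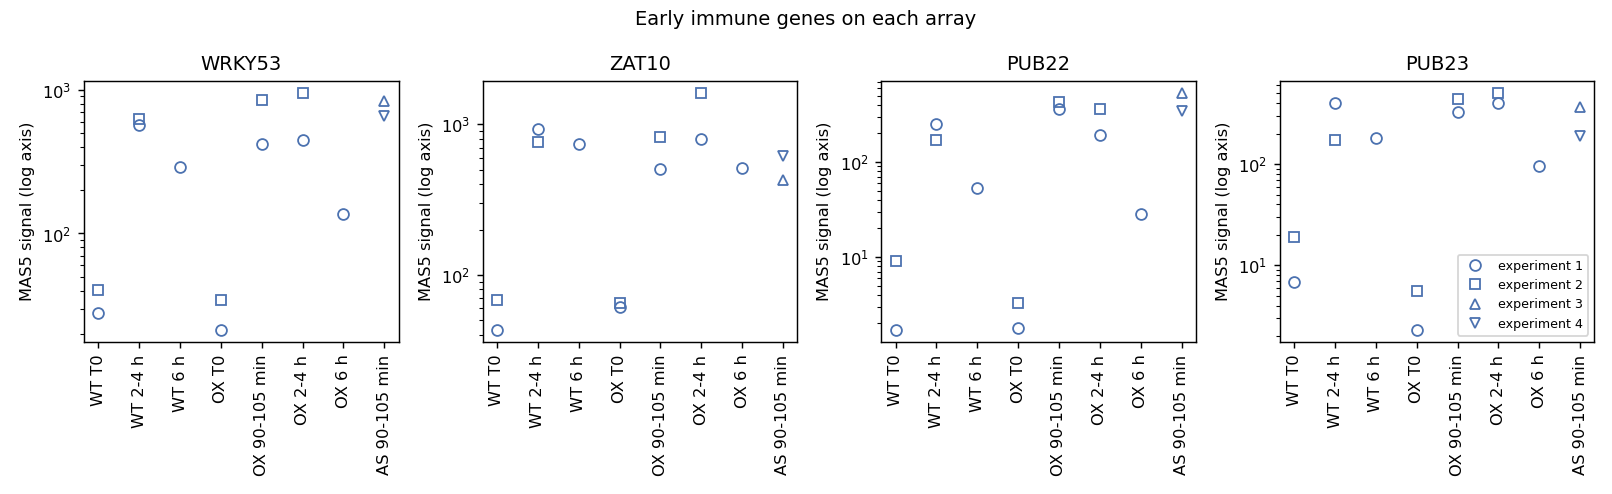
MAS5 signal (log axis) of WRKY53, ZAT10, PUB22 and PUB23 on each of the 14 arrays, grouped by line and harvest; each point is 1 array. The 4 T0 arrays lie below the inoculated arrays of the 2-4 h harvest for each of the 4 genes.

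The overexpressor was sampled at 90-105 min, the earliest harvest after inoculation. AT2G43620 already stood at 2117 ± 548 (SD, n = 2) and lay below the 40th percentile on both T0 arrays, a log2 rise of at least 6.26. AT1G51820, a leucine-rich repeat receptor kinase gene, stood at 717 ± 16.1 and lay below it at T0 too (at least 5.22). AT2G38870 rose by 5.54 and AT5G64120 by 4.998. AT2G38240 and AT5G48430, below that percentile on both T0 arrays, rose by at least 5.08 and 4.73. AT2G29500, AT5G48570, AT3G22060 and AT4G20860, below it on 1 of 2, rose by 5.58, 5.13, 4.98 and 4.60 as fitted. AT1G19960 fell (-3.42 ± 0.56), and AT4G26540, a receptor kinase gene, fell from 51.95 ± 15.2 to below that percentile on both arrays (-1.50 or lower). Of the early immune list 6 of 7 rose, PUB22 by at least 4.35, PUB23 by at least 4.29, the transcription factor gene WRKY22 by 3.56 and ZAT10 by 3.07; 6 passed adjusted over the list alone (camera adjusted p = 2.59e-12; adjusted p = 0.0401 with an estimated correlation). WRKY53 rose by 3.83. The ubiquitin 3' to 5' ratio was 1.56 and 1.203 on the 90-105 min arrays and 1.58 and 1.62 at T0.

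In limma 506 probe sets rose and 104 fell at 90-105 min in the overexpressor, each the same way in both experiments, as a call nearly requires. The adjusted p was 2.19e-05 (AT2G43620) to 0.00602 (AT5G48570) among the rises named and 0.00980 for AT1G19960. Without overexpressor 90-105 min replicate 2 the count was 205 and AT5G48570 was no longer called (5.06). Without overexpressor T0 replicate 1 it was 202, AT1G19960 was no longer called (-3.23), and of the 10 largest fitted falls 9 ended without 1 array or another, AT4G26540 being the exception.

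At 2-4 h the overexpressor showed rises of the same kind as the wild type. AT2G38870 went from 28.9 ± 11.8 to 2987 ± 375 (SD, n = 2 each; 6.08 ± 0.33 on the log2 scale) and AT5G64120 from 33.4 ± 13.3 to 2816 ± 134 (5.87 ± 0.32). AT2G43620 stood at 3724 ± 144, at least 7.10 above T0, where it lay below the 40th percentile on both arrays. AT1G57630, AT5G48430 and XTH18, below it there too, rose by at least 5.001, 4.94 and 4.71. AT2G29500, AT2G17740, AT3G22060 and AT4G22470, below it on 1 of 2, rose by 5.12, 5.05, 4.89 and 4.79 as fitted. AT4G37080, AT1G15260 and AT3G51950 fell with log2 changes of -2.33, -2.11 and -2.04, and the GDSL lipase gene AT1G29660 with -2.59 ± 0.67. All 7 early immune genes rose, PUB23 by at least 4.55, PUB22 by at least 3.79 and ZAT10 by 3.88, and 7 passed adjusted over the list alone (camera adjusted p = 1.93e-11; adjusted p = 0.0401 with an estimated correlation). WRKY53 rose by 3.95 and CCR2 by at least 3.30. The ubiquitin 3' to 5' ratio was 1.35 on average, against 1.60 at T0.

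In limma 1018 probe sets rose and 671 fell at 2-4 h in the overexpressor (1095 and 487 with each array centred on its median), with adjusted p from 3.04e-05 (AT2G43620) to 0.00302 (XTH18) among the rises named and 0.0382 for AT1G29660. Of the probe sets that rose at 90-105 min, 436 rose at 2-4 h as well (32.99 from independent lists; 0.02 calls on average in unchanged simulated groups against the same T0 arrays, and 190.5 on average and at most 214 from simulated lists of the same sizes), and 82 fell at both (4.47 from independent lists, 46.5 on average and at most 57 from simulated lists of the same sizes). Part of the excess over independent lists may come from the shared T0 arrays. The count was 526 without overexpressor 2-4 h replicate 2, 801 without T0 replicate 1 and 1070 without T0 replicate 2, and AT1G29660 was no longer called at -2.73 without overexpressor T0 replicate 1, -2.45 without overexpressor T0 replicate 2 and -1.61 without overexpressor 2-4 h replicate 2. Of the 10 largest fitted falls 7 ended without 1 array or another, and of the 10 largest fitted rises 0. AT1G19960, with a log2 change of -2.37, was no longer called at -2.18 without overexpressor T0 replicate 1, -2.56 without overexpressor T0 replicate 2 and -1.76 without overexpressor 2-4 h replicate 1.

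**Figure D3:**
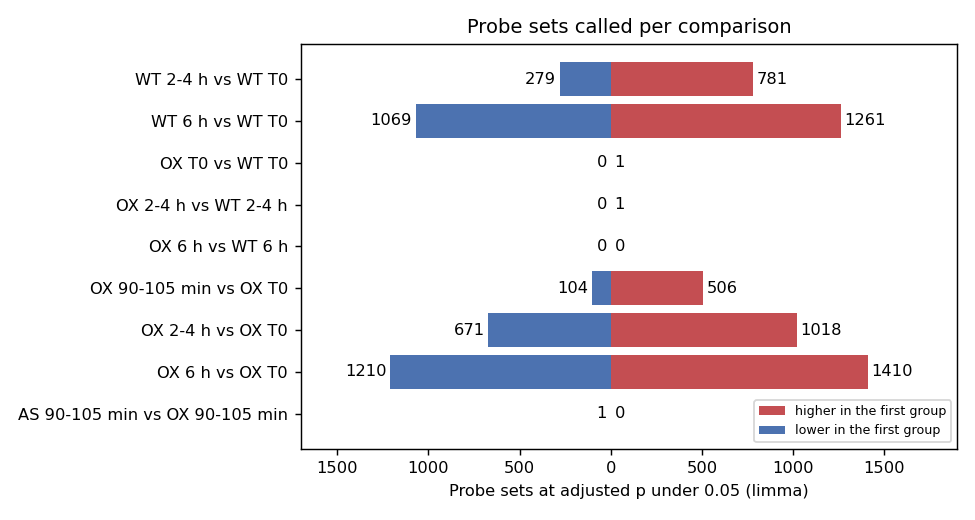
Number of probe sets that rose (right of 0) and fell (left of 0) in limma at an adjusted p under 0.05, for each comparison. The 5 comparisons with T0 within a line hold 610 to 2620 calls, and those between lines hold 0 or 1.

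The single 6 h array of the overexpressor had AT2G43620 at 2606, and this gene, UGT76B1, AT1G57630, AT2G32190 and AT3G18250, all below the 40th percentile on both T0 arrays, rose by at least 6.59, 6.48, 6.37, 5.68 and 5.60. AT5G35970 fell from 1238 ± 276 to 90.8 (SD, n = 2 at T0; -3.54 ± 0.51), and AT5G03120 and the sugar transporter gene AT1G19450 fell with log2 changes of -3.28 and -2.83. Of the early immune list 5 of 7 rose, ZAT10 by 2.75, PUB23 by at least 2.32, PUB24 by 1.76 and BIK1 by 1.52; 6 passed adjusted over the list alone (camera adjusted p = 6.50e-05; adjusted p = 0.185 with an estimated correlation). AT2G04400 rose by 2.97. The 8 measured genes of the photosynthesis list were lower as a set (camera adjusted p = 0.0380; adjusted p = 0.835 with an estimated correlation, and 0.0684 with quantile normalization, which with 0.0106 under the replicate block spans the alternatives tried as 0.0106 to 0.835), with a median log2 change of -1.09; 0 of them passed over all probe sets in limma and 3 adjusted over the list alone. The ubiquitin 3' to 5' ratio was 1.22 on the 6 h array and 1.60 on average at T0.

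In limma 1410 probe sets rose and 1210 fell at 6 h in the overexpressor (1560 and 961 with each array centred on its median), with an adjusted p of 1.02e-04 for AT2G43620 and 0.00221 for AT5G35970. Of those that rose at 2-4 h, 745 also rose at 6 h (91.9 from independent lists, 318 on average and at most 350 from simulated lists of the same sizes against the same T0 arrays; part of the excess may come from those arrays). Without overexpressor T0 replicate 2 the count was 1711, and of the 5 largest fitted falls 2 ended without 1 array or another.

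The overexpressor was set against the wild type at T0, 2-4 h and 6 h to find what AtMYB30 overexpression changes before and after inoculation. The unnamed probe set was higher by a log2 difference of 4.95 ± 0.46 at T0 (adjusted p = 0.0176; higher on both overexpressor arrays), 5.29 ± 0.46 at 2-4 h (adjusted p = 0.00975) and 5.24 ± 0.22 averaged over the 3 harvests (adjusted p = 1.48e-05; higher in 5 of 5 pairs), and it was the only probe set called in each. No gene with a name passed. Genes singled out after their values were seen were AT2G37110, a PLAC8-family gene, with 269 to 1085 in the wild type and 9.7 to 406 in the overexpressor (log2 difference at T0 -3.47 or lower, both overexpressor T0 arrays being below the 40th percentile; adjusted p = 0.207), and the glycine-rich protein gene AT2G05540, with 226 to 616 and 868 to 2098 (averaged 2.06 ± 0.27, adjusted p = 0.142). At 2-4 h the 7 early immune genes had log2 differences of -0.05 to 0.73, with 0.43 for ZAT10 and 0.10 for BIK1, and WRKY53 of the salicylic acid list 0.13; 0 of the 7 passed, also adjusted over the list alone. As a set those 7 genes were higher in the overexpressor at 2-4 h (camera adjusted p = 0.0470; adjusted p = 0.646 with an estimated correlation and 0.0758 with quantile normalization, within 0.0306 to 0.646 over the alternatives). That excess differed between the experiments. In experiment 1 ZAT10 had a signal of 806.1 in the overexpressor and 930.4 in the wild type. PUB22 had 194.6 and 254 there, WRKY22 170.8 and 228 and PUB23 402.9 and 405.3. In experiment 2 these genes had 1621 and 763.3, 364.1 and 172.5, 297 and 163, and 504.8 and 171.1. BIK1 and PUB24 were higher in the overexpressor in both. At 6 h, with 1 array against 1, the log2 differences of the 7 genes were -0.81 to -0.09 and that of WRKY53 -0.999. A set test cannot tell the lines from the deviation of a single array there.

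In limma 1 probe set was higher and 0 were lower at T0 (309 at an unadjusted p under 0.05, where chance alone gives 781), 1 and 0 at 2-4 h (287), 0 and 0 at 6 h (183) and 1 and 0 averaged over the harvests (645). Wild-type and overexpressor arrays of an experiment deviated alike (r = 0.744 at T0 and 0.490 at 2-4 h), and this fit does not pair them. Shared deviations then count as spread, so the test between lines is conservative, and few calls do not show that the lines are alike. The replicate block below assumes 1 shift per experiment at all harvests, which did not hold for 1240 probe sets. No test given here paired the lines within each experiment and harvest. At 6 h the unnamed probe set stood at 5.72 (adjusted p = 0.105), from 1 array against 1 with no replicate check. Without 1 array the T0 call ended, with 5.32 without wild-type T0 replicate 1, 4.58 without wild-type T0 replicate 2, 5.16 without overexpressor T0 replicate 1 and 4.75 without overexpressor T0 replicate 2, and so did the 2-4 h call, with 5.57 without wild-type 2-4 h replicate 1, 5.01 without wild-type 2-4 h replicate 2, 5.66 without overexpressor 2-4 h replicate 1 and 4.92 without overexpressor 2-4 h replicate 2, while the averaged call held without any of the 10 arrays. With experiment as a replicate block the averaged difference counted 4 probe sets: the unnamed one, AT2G05540 (2.06 ± 0.13), the amine oxidase gene AT1G31710 (-1.44 as fitted, with 4 of 5 overexpressor arrays at or below the 40th percentile) and AT3G12710 (-1.18 as fitted, with 1 of 5). As the mean of the 3 per-harvest differences over all arrays it counted 3: the unnamed probe set, AT2G37110 (-3.19 as fitted, with 2 of 5) and the subtilisin-like protease gene AT2G39850 (-1.15). On simulated arrays of these group sizes a 2-fold difference was found in 20% of changed probe sets at 2-4 h and 80.6% in the average, and a 4-fold difference in 86.8% and 97.8%. Those arrays were drawn without shared experiments, so the shares need not hold for the real ones.

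Whether the lines responded to inoculation alike was asked of the changes from T0 to 2-4 h. Among genes above the 40th percentile on these arrays, AT5G64120 changed by 4.84 in the wild type and 5.87 in the overexpressor, ZAT10 by 3.61 and 3.88, WRKY53 by 3.62 and 3.95 and AT1G19960 by -3.21 and -2.37. The probe sets called in the wild type all had the same sign in the overexpressor, and of those called in the overexpressor 99.3% had the same sign in the wild type. Of the rises 714 were shared (50.9 from independent lists) and of the falls 192 (11.99). Arrays of an experiment deviated alike in both lines (r = 0.744 at T0 and 0.490 at 2-4 h). Part of the excess over independent lists may thus come from the shared experiments. Across all probe sets, which are not independent replicates, the log2 changes of the lines correlated at Pearson r = 0.908 and Spearman rho = 0.802. Within experiment 1 alone r was 0.886 and within experiment 2 alone 0.819, whereas r between the lines across different experiments was 0.554 and 0.642, and r between experiments 1 and 2 within a line 0.565 in the wild type and 0.624 in the overexpressor.

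The test of the difference itself called 0 probe sets in limma (171 at an unadjusted p under 0.05), so no gene was shown to respond differently. It does not pair the lines by experiment either and is conservative, so it does not show that the responses were alike. The early immune genes rose more in the overexpressor as a set (camera adjusted p = 0.0109; adjusted p = 0.471 with an estimated correlation), with a median difference of 0.33 on the log2 scale and 0 of 7 members called, also adjusted over the list alone. The experiments differed in this. In experiment 1 ZAT10 went from 42.9 to 930.4 in the wild type and from 61 to 806.1 in the overexpressor. WRKY22 went from 22.5 to 228 and from 23.9 to 170.8 there. In experiment 2 ZAT10 went from 67.7 to 763.3 and from 64.7 to 1621, and WRKY22 from 47.7 to 163 and from 28.6 to 297. BIK1 rose more in the overexpressor in experiment 1 alone, and PUB24 in both. Of the 7 early immune genes PUB22 and PUB23 lay at or below the 40th percentile on 4 and 3 of the 4 T0 arrays.

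**Figure D4:**
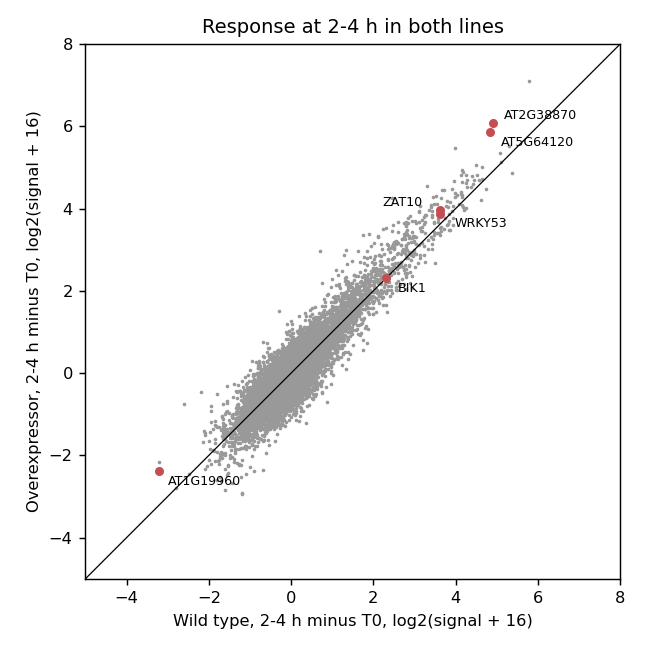
Log2 change from T0 to 2-4 h in the wild type (horizontal) and in the overexpressor (vertical) for each tested probe set, with the line of equal change; named genes are in red. AT5G64120 lies at 4.84 and 5.87 and AT1G19960 at -3.21 and -2.37.

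The antisense line was compared with the overexpressor at 90-105 min, the harvest both have. The unnamed probe set was lower, with a log2 difference of -5.66 as fitted (1 of 2 antisense arrays was below the 40th percentile; adjusted p = 0.00527; lower on both). AT2G37110 stood at 419 and 451 on the antisense arrays (3.20 ± 0.48, adjusted p = 0.335) and AT2G05540 at 27.7 and 194 (-3.82 ± 0.69, adjusted p = 0.561), neither of them called. The 7 early immune genes had log2 differences of -0.48 to 0.22, ZAT10 -0.33 and BIK1 0.18, and 0 of them passed. The 3 measured heat shock genes were higher as a set in the antisense line (camera adjusted p = 0.0162; adjusted p = 0.606 with an estimated correlation), AT1G53540 by 1.55 and AT5G37670 by 1.11, with 0 of 3 called, also adjusted over the list alone. The 3' to 5' signal ratio of the GAPDH control was 1.06 in the antisense arrays and 0.888 in those of the overexpressor.

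In limma 0 probe sets were higher and 1 was lower in the antisense line (542 at an unadjusted p under 0.05), and that call of the unnamed probe set ended, at -5.75 without overexpressor 90-105 min replicate 1 and -5.57 without overexpressor 90-105 min replicate 2 as fitted. The antisense arrays are experiments 3 and 4 and the overexpressor arrays experiments 1 and 2, so line and experiment cannot be told apart here.

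The series was designed as a screen for candidate targets of AtMYB30: genes that rise in the wild type after inoculation, are higher in the overexpressor than in the wild type and are lower in the antisense line than in the wild type. The last criterion could not be computed because wild-type arrays at 90-105 min were not analysed here, so the antisense line was set against the overexpressor. A gene raised in the overexpressor alone also meets that comparison, so it shows no effect of the antisense line. AT5G52810, which acts in pipecolic acid synthesis (SARD4), came nearest. It rose by 1.69 ± 0.39 (SE) in the wild type at 2-4 h, was higher in the overexpressor than the wild type by 1.51 ± 0.39 at that harvest (unadjusted p = 0.00335, adjusted p = 0.9999) and differed by -1.86 ± 0.39 between the antisense line and the overexpressor (unadjusted p = 8.51e-04, adjusted p = 0.916), each with 2 arrays a group and in limma. AT5G47730, AT3G51450 and 2 probe sets without a name passed these comparisons at an unadjusted p under 0.05 in limma too, with differences between overexpressor and wild type of 0.61, 0.57, 0.58 and 0.52. The signal of AT5G52810 was already 63 and 99.5 on the overexpressor T0 arrays, against 36.7 and 28.4 in the wild type. On the antisense arrays at 90-105 min it was 97 and 80.3. These genes were singled out after their values were seen.

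At an adjusted p under 0.05 limma called 781 probe sets for the first criterion and 1 for the second, and 0 for both (independent lists give 0.05002); taking the second at T0 or over the 3 harvests also gave 0. At an unadjusted p under 0.05, chosen after the data were seen, 40 met both (1583 and 144, with 14.6 from independent lists), 5 of them lower in the antisense line than in the overexpressor. These overlaps were set against 50 simulated draws of independent arrays that kept the response and made the lines alike, also chosen after the data were seen. At the same p the draws gave longer lists (2126 and 386 on average), and a mean of 40.98 and at most 55 met both, 2.54 and at most 7 of them lower in the antisense line. Lists of the observed sizes from the top of each draw shared a mean of 13.5 and at most 21, with 0.68 and at most 4 lower in the antisense line. The overlap thus exceeded the draws for lists of its sizes but not at its p. The draws lack the deviations that real arrays of an experiment share, so neither comparison decides whether chance gave the overlap. No difference between the lines is read from it. With a 2-fold difference required in each experiment 2 met both, AT5G52810 and a probe set without a name, of which AT5G52810 was also lower in the antisense line than in the overexpressor. The wild-type 2-4 h arrays enter the criteria with opposite signs, which lowers the overlap that chance gives.

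Gene groups were read from 21 lists fixed before the data were examined. Beside the early immune genes, 1 or 2 genes of some other lists were called. The aliphatic glucosinolate genes BCAT4 and AT2G31790, which encode an aminotransferase and a glucosyltransferase of that pathway, both fell at 6 h in the wild type (-2.15 and -1.29) and in the overexpressor (-2.39 and -1.41), 2 of 2 adjusted over the list alone at each. AT2G31790 also fell at 2-4 h in the overexpressor (-0.99). Of the phenylpropanoid genes both rose at 2-4 h in the wild type, HCT by 1.44 and CCR2 by at least 2.49. CCR2, below the 40th percentile on all 4 T0 arrays, also rose by at least 1.02 at 90-105 min, 3.30 at 2-4 h and 1.87 at 6 h in the overexpressor and 2.21 at 6 h in the wild type. AT2G04400 of the tryptophan list rose at 2-4 h in the wild type (1.21) and the overexpressor (1.47). FAMA, a guard cell transcription factor gene, fell at 6 h in the wild type (-1.03). WRKY53 of the salicylic acid list rose in all 5 comparisons with T0, at 6 h by 2.62 in the wild type and 1.83 in the overexpressor. Each of these comparisons carries the difference in the ubiquitin 3' to 5' ratio given above.

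Some of these calls ended without 1 array. AT2G04400 stood at 1.39 without wild-type T0 replicate 1, 1.03 without wild-type T0 replicate 2 and 0.96 without wild-type 2-4 h replicate 2 in the wild type and at 1.28 without overexpressor 2-4 h replicate 2 in the overexpressor. HCT stood at 1.04 without wild-type T0 replicate 1, 1.49 without wild-type 2-4 h replicate 1 and 1.39 without wild-type 2-4 h replicate 2. CCR2 at 90-105 min stood, as fitted, at 1.74 without overexpressor T0 replicate 1, 1.68 without overexpressor T0 replicate 2 and 1.29 without overexpressor 90-105 min replicate 2. BCAT4 at 6 h stood at -1.97 without wild-type T0 replicate 2 and at -1.93 without overexpressor T0 replicate 1. AT2G31790 stood at -1.15 without wild-type T0 replicate 2 at 6 h and, in the overexpressor at 2-4 h, at -0.84 without overexpressor T0 replicate 1, -1.13 without overexpressor T0 replicate 2, -1.08 without overexpressor 2-4 h replicate 1 and -0.90 without overexpressor 2-4 h replicate 2. FAMA stood at -0.96 without wild-type T0 replicate 1 and -1.09 without wild-type T0 replicate 2. WRKY53 at 6 h in the overexpressor stood at 1.61 without overexpressor T0 replicate 1 and 2.04 without overexpressor T0 replicate 2, and WRKY22, which rose by 2.52 at 2-4 h there, at 2.15 without overexpressor 2-4 h replicate 2.

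Other lists held no call over all probe sets in the comparisons with T0. The heat shock genes AT1G53540 and AT5G37670, below the 40th percentile on all 4 T0 arrays, had log2 changes of at least 3.85 and 2.02 at 2-4 h in the wild type, 4.58 and 2.11 at 90-105 min and 4.16 and 1.75 at 2-4 h in the overexpressor, with 2 of 3 passing adjusted over the list alone at each of these. Under the alternatives their changes are given as fitted. In the overexpressor AT1G53540 passed at 90-105 min and 2-4 h with a pseudocount of 1 (5.74 and 5.28) and with a random block (4.58 and 4.16). From the arrays of the compared groups alone AT1G53540 (4.58) and AT5G37670 (2.11) passed there at 90-105 min. AT5G37670 passed in the wild type at 2-4 h without 2-4 h replicate 1 (3.01) and AT1G53540 in the overexpressor at 2-4 h without 2-4 h replicate 1 (5.81). In the wild type at 2-4 h AT5G37670 ranged from 1.02 to 3.01 and AT1G53540 from 2.16 to 5.54 when 1 array was left out. Both were lowest without wild-type 2-4 h replicate 2. With experiment as a replicate block AT1G53540 passed in all 5 comparisons with T0 (3.85, 4.30, 4.58, 4.16 and 4.27) and AT5G37670 at 6 h in the wild type (2.36), and in the overexpressor at 6 h the dehydrin gene COR47 (-2.46 against -1.84), FAMA (-0.79 against -0.69) and the defensin gene PDF1.2 (-1.66 against -1.02). COR47 also passed there without overexpressor T0 replicate 2 (-2.995). The block takes 1 shift per experiment for all harvests. The shift from experiment 1 to 2 was 0.33 at T0 and 3.34 at 2-4 h for AT1G53540, and -2.07 and -0.87 for COR47. The values of AT1G53540 and COR47 with the block, above all at 6 h, thus rest on an assumption that did not hold for them. For AT5G37670, with shifts of -0.0024 at T0 and 1.66 at 2-4 h, it did not hold either. FAMA and PDF1.2 were not among the genes whose change from T0 to 2-4 h was called different between the experiments. Also with that block the heat shock set was higher at 2-4 h in the wild type (camera adjusted p = 0.0361; 0.113 without the block, and 0.0361 to 0.835 over the alternatives) and the photosynthesis set lower at 6 h there (camera adjusted p = 0.0311; 0.103 without, and 0.0311 to 0.835 over the alternatives).

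For the remaining lists, log2 changes at 2-4 h in the wild type are given with their range when 1 of the 4 arrays was left out. FATB, the 1 tested gene of the wax and cutin list, had -0.60 (-0.75 to -0.46). Its unadjusted p in limma was under 0.05 here and in the overexpressor at 2-4 h (-0.64). Adjusting over a list of 1 gene changes nothing. The sphingolipid gene LCB2 had -0.36 (-0.46 to -0.25), and the jasmonate genes OPCL1 and PDF1.2 had 0.69 (0.47 to 0.92) and -0.32 (-1.37 to 0.74). COR15A and COR47 of the abscisic acid and cold list had 1.16 (-1.48 to 3.81) and -0.45 (-1.37 to 0.47), and EXPA8 and BIM1 of the brassinosteroid list -1.31 (-2.04 to -0.58) and -1.18 (-1.89 to -0.47). The clock gene GI had -0.07 (-1.91 to 1.78) and the vascular list's sugar transporter gene SWEET11 0.40 (-0.39 to 1.18). None passed over all probe sets in the fit as planned, and the sign of PDF1.2, COR15A, COR47, GI and SWEET11 turned without 1 T0 array. Calls were gained when the T0 arrays of 1 experiment were left out in both lines, a setting chosen after the data were seen. At 2-4 h in the wild type COR15A then rose without experiment 1 (3.81 as fitted), and without experiment 2 BIM1 (-1.89) and GI (-1.91) fell and SWEET11 (1.18) rose. In the overexpressor at 2-4 h COR15A (4.60) and GI (1.99) passed without experiment 1 and BIM1 (-1.62) without experiment 2, and at 90-105 min COR15A (5.31) and GI (-2.80), without experiments 1 and 2 in that order. At 6 h GI passed in both lines without experiment 1 (2.36 in the wild type and 2.44 in the overexpressor) and COR15A (-4.71 and -3.78), COR47 (-2.13 and -2.995) and BIM1 (-1.97 and -1.61) without experiment 2. The sign of GI thus followed the experiment left out, and so did that of COR15A at 2-4 h and 6 h. At 90-105 min COR15A had signals of 1494 and 642 in the overexpressor, against 729 and 9.1 at T0, and its sign did not turn. The trichome gene TRY lay at or below the 40th percentile on 3 of these 4 arrays, so no change is given for it. Adjusted over the list alone, 2 of 2 glucosinolate genes were lower at 2-4 h in the wild type and 2 higher in the antisense line than in the overexpressor, and 1 of 2 guard cell genes was lower at 2-4 h in the wild type. The 1 tested tryptophan gene was higher in the overexpressor than in the wild type at 2-4 h at an unadjusted p under 0.05 in limma. It did not pass over all probe sets. The jasmonate, abscisic acid and cold, brassinosteroid, clock, trichome, vascular and sphingolipid lists had 0 genes that passed adjusted over the list alone. Of 378 list genes 46 had a named probe set, under 80% of every list, so no list stands for its pathway; the elongase, ethylene and flower lists had 0 named members and the cell death and flavonoid lists 0 tested. Camera called 10 of 55 tests over the 5 lists with at least 3 tested members, and 3 with an estimated correlation, those of the early immune list at 2-4 h in both lines and at 90-105 min. Of the 10, 1 is the 6 h difference between the lines, which rests on 1 array each.

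Experiments 1 and 2 were also set against each other, in a comparison added after the data were examined, over the 8 arrays of both lines at T0 and 2-4 h. The lines served as replicates of each experiment here, so the calls do not measure how far experiments vary. At T0 the clock gene GI had a mean signal of 786 in experiment 1 and 46.1 in experiment 2 (n = 2 each, 1 array per line), and the cold-responsive gene COR15A 1539 and 26.8. At 2-4 h the small heat shock protein gene AT1G53540 had 129 in experiment 1 and 1449 in experiment 2. Across probe sets limma called 1406 higher and 1243 lower in experiment 2 at T0, 171 and 310 at 2-4 h, and 1240 whose change from T0 to 2-4 h differed between the experiments. Those 1240 hold 47 of the 1060 probe sets called at 2-4 h in the wild type and 69 of the 1689 called in the overexpressor. Both are smaller shares than 1240 of the 15615 tested. In the comparisons with T0 the experiments are the replicates, so a probe set that differs between them has a wide spread and is less likely to be called. The low counts thus do not show that the calls are free of the difference between experiments.

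**Figure D5:**
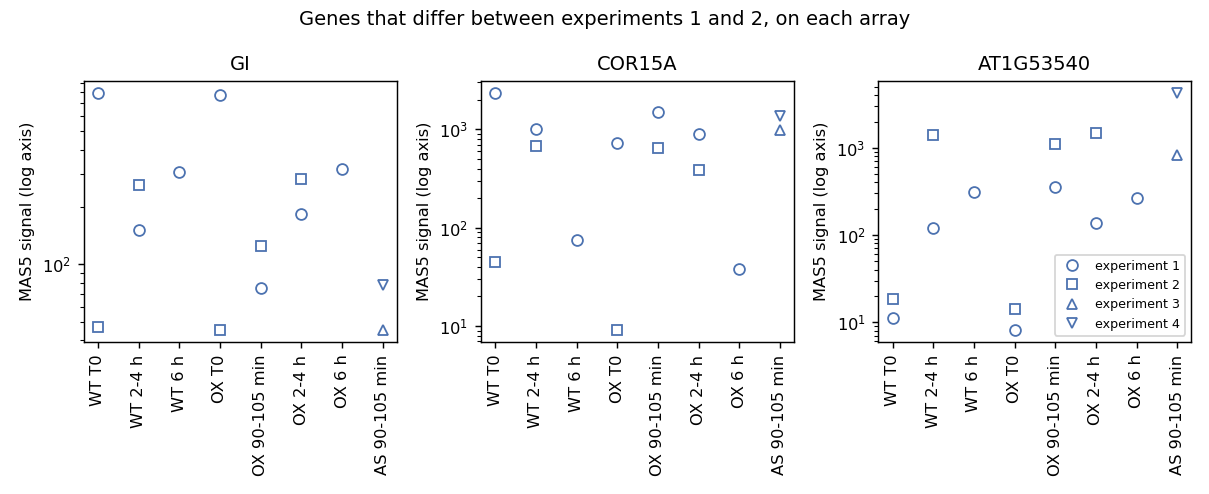
MAS5 signal (log axis) of GI, COR15A and AT1G53540 on each of the 14 arrays, grouped by line and harvest, with a symbol for each experiment. At T0 both lines have GI far higher in experiment 1, at a mean of 786, than in experiment 2, at 46.1.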

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

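The tests of a failed array, of inoculated leaves among the T0 samples and of RNA quality were chosen only after the results were seen, and so was the comparison of experiments; the counts of other splits of the samples were chosen before. The change from T0 to 2-4 h was compared between experiments 1 and 2 over both lines, as a difference tested in limma on 8 arrays, and 10 of 57 named genes differed. The arrays of the lines served as replicates of an experiment. The errors thus measure the spread between lines within an experiment and not how far experiments vary.

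GI, a clock gene, differed most: its log2 change in experiment 2 minus that in experiment 1 was 4.33 ± 0.24 (SE), with a mean signal at T0 of 786 in experiment 1 and 46.1 in experiment 2. The cold-responsive gene COR15A differed by 4.23 (1539 and 26.8 at T0), and the dehydrin gene COR47 by 1.21 (4993 and 1212). BIM1, a brassinosteroid signalling gene, differed by 1.29 (169.8 and 63 at T0), and AT4G23670 by 1.66 (641 and 247). For the small heat shock protein genes the difference lay at 2-4 h: AT1G53540 differed by 3.01 (129 in experiment 1 and 1449 in experiment 2 at 2-4 h), AT5G37670 by 1.67 (48.9 and 194) and AT2G29500 by 1.19 (606 and 1978). AT1G22690 differed by -1.97 (543 and 160.0 at 2-4 h) and AT1G54820 by -1.32 (63.4 and 29.4). These sizes are as fitted: AT1G53540, AT5G37670, AT2G29500 and COR15A lay at or below the 40th percentile on 4, 4, 3 and 1 of the 4 T0 arrays.

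The experiments differed more at T0 (2649 probe sets called) than at 2-4 h (481). A single failed array is argued against, since the T0 difference correlated across probe sets between the wild type and the overexpressor at r = 0.744. Inoculated leaves among the T0 samples are argued against too: on the mean log2 level of the 7 early immune genes the lowest inoculated array lay 1.38 above the highest T0 array, and the 4 T0 arrays spanned 0.29. RNA quality stays open, because 1 of the 3 control genes had a 3' to 5' signal ratio that differed between experiments the same way in both lines. The hour of harvest or the temperature before it may differ between experiments, as the clock gene GI and the cold-responsive COR15A would allow, but the labels give neither and this was not tested.

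The single call of the overexpressor against the wild type over 3 harvests, the unnamed probe set, was set against the other ways of splitting the 10 arrays within harvests: 1 of 36 splits, the real one, gave a call, and the highest other gave 0, so a chance split did not give such a call, 1 in 36 being the smallest share that can be reached. At an unadjusted p under 0.05 the real split counted 645 probe sets, 15 of 36 splits as many, and the highest other 3004, so chance cannot be excluded for that count. That highest split follows experiments 1 and 2, a structure of the samples, and with experiment as a block the real split called 4 probe sets. Among the 16 splits that part all 5 pairs the real one had 645 and the highest other 417, and 16 splits are too few for a share under 0.05; the others mix the lines between experiments or harvests.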

How the results depend on the processing

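The settings that leave out T0 or 2-4 h arrays of 1 experiment, and the screen at an unadjusted p or a 2-fold difference, were chosen after seeing the data. Total counts of calls stayed within 1.5 times under no filter, the stricter filter, median centring, quantile normalization, no trend and the 2-fold minimum. Falls alone moved further: in the wild type at 2-4 h 169 with no filter, 181 with the 2-fold minimum and 462 with a random block, against 279; in the overexpressor 392 with the 2-fold minimum at 2-4 h, against 671, and 227 with a random and 220 with a fixed block at 90-105 min, against 104. The cause of these and of the exceptions below was not tested unless named. With a pseudocount of 1 the overexpressor against the wild type had 0 calls at T0 and 0 at 2-4 h, and with 64 it had 2 at 6 h. The average over harvests had 4 with the replicate block, 2 with a random block and 3 as the mean of the 3 per-harvest differences. From the arrays of the compared groups alone, where fewer arrays estimate the spread, calls were 410 (wild type 2-4 h), 134 (wild type 6 h), 0 (overexpressor against wild type at T0), 145 (overexpressor 90-105 min), 570 (2-4 h), 0 (6 h) and 0 (antisense against overexpressor).

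Without the T0 arrays of experiment 1 calls were 678 (wild type 2-4 h), 0 (overexpressor against wild type at T0) and 297 (overexpressor 90-105 min), and without those of experiment 2 they were 0 (overexpressor against wild type at T0) and 1442 (overexpressor 90-105 min). Without the 2-4 h arrays of experiment 2 they were 292 (wild type 2-4 h), 0 (overexpressor against wild type at 2-4 h) and 444 (overexpressor 2-4 h). GI in the overexpressor at 2-4 h against T0 turned to -1.70 without the T0 arrays of experiment 2, which leaves the T0 array where its signal was high. The screen counted 40 at an unadjusted p and 2 at a 2-fold difference, and 3 list tests passed with an estimated correlation. Leaving out each array in turn gave 367 to 599 (wild type 2-4 h), 1342 to 1837 (wild type 6 h), 202 to 628, 526 to 1158 and 1711 to 1898 (overexpressor, earliest to latest harvest), 0 to 0 and 0 to 0 (between lines at T0 and 2-4 h), 1 to 1 (average), 0 to 1 (antisense), 0 to 0 (difference of responses) and 0 to 0 (screen); fewer arrays enter each.

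With experiment as a replicate block calls were 1335 and 3038 in the wild type at 2-4 h and 6 h, 898, 2035 and 3261 in the overexpressor from the earliest to the latest harvest, and 1, 1 and 0 between the lines; beyond the average, the gene calls and the set calls given with the results, the block ended the calls of HIS1-3 (wild type 2-4 h, as fitted -1.94) and AT1G54820 (overexpressor 90-105 min, -1.82) and changed no other named one. No paired analysis was possible for the antisense line because it shares no experiment number with the others, and for 6 h between lines the compared arrays alone leave no residual degrees of freedom; no alternative was run for AtMYB30, which has no named probe set. Over single named genes, 1564 values kept their side of the threshold without 1 array, of which 225, never called, turned sign, 103 lost a call and 3 gained one; under the other settings these were 4814, 82, 155 and 38. Signals near the 40th percentile of an array, 16.6 to 19.9, cannot be told from background without detection calls, which limits what can be said of low genes.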

Other observations

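The comparisons in this part and the gene families were chosen after the data were seen. Between 2-4 h and 6 h the wild type and the overexpressor gained AT3G13610, which encodes the feruloyl-CoA hydroxylase of scopoletin synthesis: it rose to 380.4 in the wild type (by at least 3.99 on the log2 scale, from below the 40th percentile on both 2-4 h arrays; adjusted p = 5.57e-04) and to 619.6 in the overexpressor (4.12 as fitted, below it on 1 of 2; adjusted p = 3.84e-04), from 1 array at 6 h. UGT76B1 rose by 3.84 and 3.94, AT1G43910 by 3.47 and 3.85, and UGT73D1, below that percentile on the 2-4 h arrays, by at least 2.93 and 3.46. PUB22 fell in the overexpressor (-2.67), as did AT5G55180 (-3.08). From 90-105 min to 2-4 h the overexpressor gained the calmodulin-like gene CML37 and UGT76B1, below it on both 90-105 min arrays (at least 3.11 and 2.82), and AT5G18470 and AT3G18250, below it on 1 of 2 (3.54 and 3.43 as fitted). In limma 82 probe sets rose and 3 fell in the wild type from 2-4 h to 6 h, 110 and 46 in the overexpressor, and 68 and 7 there from 90-105 min to 2-4 h. No alternative settings were run for these.

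Among 20 gene families taken from symbols, the calmodulin-like genes were higher as a set at 2-4 h in the wild type (3 of 7 called; camera adjusted p = 1.19e-04; adjusted p = 0.406 with an estimated correlation) and in the overexpressor (3 of 7; camera adjusted p = 3.50e-04; adjusted p = 0.406 with an estimated correlation), and the U-box ubiquitin ligase genes at 90-105 min in the overexpressor (2 of 8; camera adjusted p = 0.00211; adjusted p = 0.434 with an estimated correlation) and at 2-4 h in the overexpressor (3 of 8; camera adjusted p = 0.0294; adjusted p = 0.480 with an estimated correlation) and the wild type (3 of 8; camera adjusted p = 0.0383; adjusted p = 0.480 with an estimated correlation); PUB22 and PUB23 are on the early immune list too. Plastid-encoded photosynthesis genes were lower at 6 h in the wild type, from 1 array at that harvest, with a median log2 change of -1.26 over 42 probe sets, 2 of them called (camera adjusted p = 1.19e-04; adjusted p = 0.834 with an estimated correlation); the median was -1.22 with quantile normalization and -1.18 with median centring, where 0 were called. The ubiquitin 3' to 5' ratio was 1.22 on that array and 1.57 on average at T0. In the overexpressor at 6 h, also from 1 array, the median log2 change of these 42 probe sets from T0 was -0.42. Their median difference between the overexpressor and the wild type was -0.22 before inoculation (camera adjusted p = 0.0380; adjusted p = 0.857 with an estimated correlation; medians -0.16 and -0.23 under the same scalings) and -0.38 at 2-4 h (camera adjusted p = 1.19e-04; adjusted p = 0.834 with an estimated correlation; medians -0.38 and -0.35). At 6 h it was 0.59, from 1 array against 1, which cannot tell the lines from the deviation of a single array. In limma 0 members were called between the lines. Of the 220 family tests 20 passed with the preset correlation and 0 with an estimated one.

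Differences between the overexpressor and the wild type were compared before and after inoculation. They had the same sign at T0 and at 2-4 h in 55.7% of probe sets. Of the probe sets higher in the overexpressor at an unadjusted p under 0.05, 174 at T0 and 144 at 2-4 h, 29 were in both (1.60 from independent lists), and of those lower, 135 and 143, 11 (1.24). The harvests share no arrays, but the arrays of an experiment share its conditions and all share 1 estimate of the spread. Across probe sets, which are not independent replicates, the difference at T0 and that at 2-4 h correlated at r = 0.275 (rho = 0.186). Genes with such differences, singled out after their values were seen and not called in the test as planned, were AT2G39850, a subtilisin-like protease gene, at 131 to 199.9 in the wild type and 33.4 to 92.5 in the overexpressor (averaged -1.07 ± 0.14, adjusted p = 0.142, and 0.0421 to 0.711 over the alternatives, passing as the mean of the per-harvest differences), the GDSL lipase gene AT1G75900 (averaged 1.13 ± 0.18, adjusted p = 0.245) and AT5G52810 (averaged 1.31 ± 0.23, adjusted p = 0.245).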
